A study of Homo sapiens with 22 samples.

How the data were processed

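Tag-seq break lists of MCF7 genomic DNA from 22 libraries were used: 3 libraries each of hpCasMINI, LbCas12a, SpCas9, hpOsCas12f1, enOsCas12f1, hpAsCas12f1 and AsCas12f1, and 1 of CasMINI. Per the labels, cells in multi-well plates received 490 ng of guide RNA plasmid and 10 ng of nuclease plasmid; the protocol names CasMINI, hpCasMINI, SpCas9 and LbCas12a, and the same text is attached to the OsCas12f1 and AsCas12f1 libraries. The deposited files give counts, that is, whole numbers of reads per genomic position and orientation class, unnormalised, in 1 list per library. Coordinates are on hg38 per the submitters' processing notes, and positions are printed 1-based. The aligner, the break caller, duplicate handling and any filter are not given in the sources used here. The name field holds 2 orientation words that the sources do not define, and the second was used as read direction. Where the reference sequence starts, a leftward read has no room, and there the second word was plus at all 182 listed positions within 20 bp of base 10000 of the chromosomes and at all 10 within 20 bp of the start of an unplaced contig, while the first word was plus at 90 and 3 of them; this check was added after the data were seen. That field also holds a whole number whose meaning the sources do not give, and it was not used here.

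Positions on a chromosome within 50 bp of each other were joined into 2430676 sites. A site was called for a nuclease when at least 2 of its 3 libraries (for CasMINI, its 1 library) held at least 5 reads and both read orientations were present. Values are on the reads-per-million scale of the list's total (RPM), because factors fitted on cleaved sites would remove a uniform change of activity. Genes were named from a RefSeq table of assembly GRCh38.p14, the same build, by the gene that holds the position with the most reads, or else the nearest gene. These choices, the comparisons, the tests, the gene lists and the rule for named sites were made before the data were examined.

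The planned rule for target and off-target sites rested on a PAM and on mismatches to the guide. Neither a genome sequence nor guide sequences were in the sources, so this part was not run, and a rule chosen after the data were seen took its place. A break was called two-sided when leftward reads started at a left end and rightward reads at a right end from -10 to 60 bp away, starts within 10 bp being pooled, the weaker end holding at least 10.0% of both ends' reads and both ends together at least 30.0% of the site's reads. The opposite arrangement, with rightward reads starting left of leftward reads, is called facing. Target loci of SpCas9, LbCas12a and the CasMINI pair were sites with a two-sided break in at least 2 of these 3 families and at least 1000 RPM in at least 2 of them. Loci called in every nuclease were kept, against the written clause, which is given as an alternative. For the OsCas12f1 and AsCas12f1 pairs, target loci were the 10 sites with the most reads among two-sided breaks whose RPM were at least 10 times the median of the other families, floored at 1, or that were target loci of the other nucleases. Candidate off-target sites were the remaining two-sided breaks of a nuclease with 3 libraries that met the same 10-fold criterion and lay over 5 kb from a target locus. The geometry was tested on simulated data: 100% of 500 simulated two-sided breaks and 0% of 500 sites with spread positions were called two-sided, while 48.4% of the latter were called facing.

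Single values of 3 against 3 libraries were compared with two-sided exact permutation tests of the difference in means, whose smallest p is 0.1. Shares of the single CasMINI library carry exact Clopper-Pearson 95% intervals. Reads per site were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, list totals as library sizes, sites with at least 10 reads over the 6 libraries, Benjamini-Hochberg adjusted p under 0.05). In each of the 5 planned fits the prior degrees of freedom were infinite, so that every site took the spread of the trend; 62.3% of tested sites in the AsCas12f1 pair and 94.0% to 96.6% in the other comparisons had reads in 1 library. A fit requiring reads in at least 3 of the 6 libraries was therefore added after the data were seen. Where a group had 0 reads, folds are bounds against 3 counts over that group.

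On simulated counts with a dispersion of 0.2, edgeR recovered 94 of 100 changed sites at 8-fold and 100 of 100 at 64-fold for the AsCas12f1 pair (12908 sites simulated), and 58 of 62 and 62 of 62 for the OsCas12f1 pair (53887 sites). It recovered 85 and 100 of 100 for hpCasMINI against SpCas9 (155673 sites) and likewise for hpCasMINI against LbCas12a (145060 sites), and 90 and 100 of 100 for SpCas9 against LbCas12a (95408 sites). At the spread fitted to the data it recovered 6 and 85 of 100 for the AsCas12f1 pair, 0 and 1 of 62 for the OsCas12f1 pair, and 0 and 0 of 100 in each of the other comparisons.

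Whether replicate numbers pair libraries was checked by correlating deviations from the group mean across called sites of both nucleases. Only for hpAsCas12f1 and AsCas12f1 did all 3 same-numbered pairs exceed 0.1 (0.488, 0.276 and 0.193, against -0.333 to 0.159 for pairs with different numbers), so the values with the replicate block are printed beside the sums and counts of that pair. Labels give no batch. The text names every target locus except 1, which is counted in the sums over 8 or 10 loci and in the counts of sites and is not reported here, the 3 off-target sites with the most reads per family, the 5 called sites with the largest fold in each direction whose libraries did not overlap, and the 5 hotspots called in every nuclease with the most reads. Outside that rule, every called site was named where at most 5 were called, a clause chosen after the values were seen. Gene lists were examined per library on sites called in no nuclease, as the share inside gene bodies over the share of annotated chromosome length. Fisher's exact test set the sites inside and outside the gene bodies against the counts predicted from this length. These predicted counts were entered as if they were a second sample of the same size. That tends to make p larger than in a test against a fixed expectation.

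Alternatives were other read minimums, joining distances and scalings, no orientation rule, thinning to the shallowest library, other off-target definitions, TMM factors, DESeq2 1.42.0, no filter, the replicate block, and each library left out in turn. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The distance of breaks from the PAM, mismatch counts and indel rates were not analysed here.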

Results

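Tag-seq, which marks double-strand breaks in living cells by the integration of a short DNA tag, was performed on genomic DNA of MCF7, a human breast cancer cell line of epithelial origin. The deposited lists gave the number of reads per genomic position and read orientation in 22 libraries of 8 nucleases, and values below are on the reads-per-million scale of the library total (RPM). Those nucleases were SpCas9 (Cas9 of Streptococcus pyogenes), LbCas12a (Cas12a of a Lachnospiraceae bacterium), and 3 pairs of compact Cas12f nucleases: hpCasMINI and CasMINI, hpOsCas12f1 and enOsCas12f1, and hpAsCas12f1 and AsCas12f1. Each nuclease had 3 libraries except CasMINI, which had 1. The members of a pair are called a family here, so that the 8 nucleases fall into 5 families. No untreated library was present, and the labels do not say whether libraries with different replicate numbers came from separate cultures, so each p value measures only the spread between these libraries.

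Library totals ran from 206785 to 2883211 reads. The hpCasMINI libraries held 1473182, 2168409 and 1853802 reads, and the CasMINI library held 740126 reads. For LbCas12a the totals were 896359, 992879 and 1080503 reads, and for SpCas9 they were 2159967, 2078455 and 2883211 reads. Totals of the hpOsCas12f1 libraries were 206785, 319153 and 322965 reads, against 413899, 402876 and 340634 reads for enOsCas12f1. The hpAsCas12f1 libraries had 827159, 532093 and 501471 reads and the AsCas12f1 libraries had 451713, 505398 and 559319 reads. A site with 0 reads in a library of these sizes allows up to 1.04 RPM in the deepest library and 14.5 in the shallowest, taking 3 counts as the limit. Because the sources do not say how duplicate reads were handled, these limits and the binomial intervals below cover counting error only.

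Breaks recurred at 8 loci shared by SpCas9, LbCas12a and the CasMINI pair, which the series placed at the same or adjacent positions. These loci, on build hg38, included DNMT1, the maintenance DNA methyltransferase gene (chromosome 19, 10133268 to 10134383), PPP1R12C, the host gene of a common transgene insertion locus (chromosome 19, 55115353 to 55117225), KLHL29 (chromosome 2, 23693440 to 23695644), and NLRC4, an inflammasome gene (chromosome 2, 32227455 to 32229897). They also included EMX1, a homeobox gene (chromosome 2, 72933987 to 72935527), NUDT16 (chromosome 3, 131386240 to 131388754), and an intergenic locus 82435 bp from FGF18 (chromosome 5, 171539660 to 171540867). All 8 are inferred from the breaks themselves, since neither guide sequences nor a genome sequence were in the sources used here, and a tested site that failed the rule would be counted below as off-target. The series text names 10 tested sites for CasMINI and hpCasMINI, more than the 8 loci that met the rule, so tested sites may be among the candidate off-target sites.

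The first question was whether hpCasMINI gave more on-target signal than CasMINI. At EMX1, hpCasMINI gave 1319 ± 268 RPM (SD, n = 3) and CasMINI gave 1127 in its single library, a ratio of 1.17. The ratio was 1.02 at PPP1R12C (7664 ± 1849 against 7541). It was 0.629 at NUDT16 (1394 ± 117 against 2216) and 0.688 at DNMT1 (2107 ± 197 against 3063). Near FGF18 the values were 2972 ± 283 and 3501 RPM, at KLHL29 they were 8043 ± 884 and 8361, and at NLRC4 they were 5750 ± 567 and 5931. Among these loci, all 3 hpCasMINI libraries lay above the CasMINI library at EMX1, and all 3 lay below it at NUDT16, DNMT1 and the one near FGF18. Summed over the 8 loci, hpCasMINI had 11.99% ± 1.70 of its reads on target and CasMINI had 10.1% (exact Clopper-Pearson 95% interval 10.0% to 10.2%), a ratio of means of 1.18 with no test, because CasMINI had 1 library. The lowest hpCasMINI library, at 101038 on-target RPM, lay just below the CasMINI library, at 101154. Over the 7 loci named above alone, a setting added after the data were seen, the values were 2.92% ± 0.309 and 3.17% (exact Clopper-Pearson 95% interval 3.13% to 3.21%), and the ratio turned to 0.922, so the direction of the sum depended on which loci were counted.

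**Figure D1:**
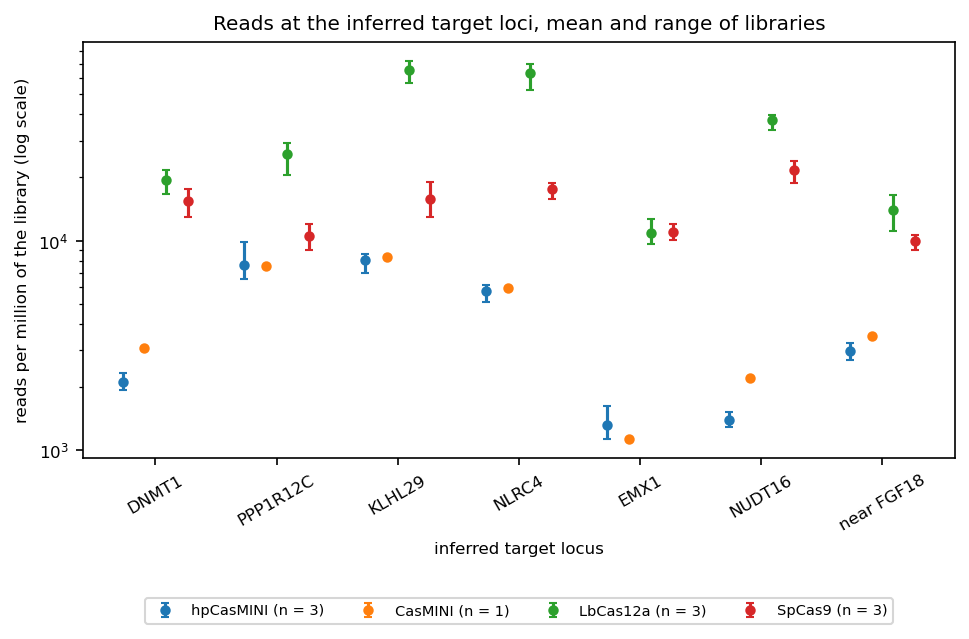
RPM (log scale) at 7 inferred target loci shared by hpCasMINI, CasMINI, LbCas12a and SpCas9, with points for the mean and bars for the range of 3 libraries (CasMINI has 1). LbCas12a has its highest mean at KLHL29, 65205 RPM.

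At the same loci, LbCas12a and SpCas9 had their own profiles. LbCas12a had its highest values at KLHL29, with 65205 ± 7821 RPM (SD, n = 3), and at NLRC4, with 62749 ± 9012. It gave 37692 ± 3582 at NUDT16 and 10818 ± 1662 at EMX1. SpCas9 gave 21620 ± 2689 at NUDT16, 17645 ± 1651 at NLRC4 and 15748 ± 3051 at KLHL29. At DNMT1 the values were 19409 ± 2490 for LbCas12a and 15469 ± 2334 for SpCas9, at PPP1R12C they were 25882 ± 4629 and 10497 ± 1515, near FGF18 they were 14019 ± 2737 and 9977 ± 834, and at EMX1 SpCas9 gave 11011 ± 1010. On-target reads made up 26.2% ± 3.31 of LbCas12a reads and 11.5% ± 1.42 of SpCas9 reads. These percentages are shares of a library, so reads elsewhere lower them. Candidate off-target sites held 581611 RPM in SpCas9 and 24398 in LbCas12a. Reads outside called sites were 20.03% to 31.7% in SpCas9 libraries, 56.6% to 59.1% in LbCas12a and 78.2% to 81.7% in hpCasMINI. On-target RPM and percentages therefore do not rank the activity of nucleases of different families.

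The second question was how specific hpCasMINI was beside SpCas9, LbCas12a and CasMINI. SpCas9 had strong recurrent breaks outside the target loci in LAMC3, a laminin gene (chromosome 9, 131049113), at 26925 ± 3375 RPM (SD, n = 3), in CNTN2, a neural adhesion gene (chromosome 1, 205058180), at 17311 ± 1488, and 5064 bp from PLA2G2D (chromosome 1, 20124437), at 16226 ± 1481. LbCas12a had one such site above all its others, 67935 bp from the taste receptor gene TAS2R1 (chromosome 5, 9971559), at 15408 ± 1076, followed by a site 3678 bp from NCAN (chromosome 19, 19208210), at 2333 ± 308, and one in RNF213 (chromosome 17, 80320598), at 1544 ± 471. The strongest hpCasMINI site lay 680 bp from CDC42EP4 (chromosome 17, 73312603) and had 717 ± 333 RPM against 230 in CasMINI. The next lay 56909 bp from ENOX2 (chromosome X, 130565315), with 218 ± 131 in hpCasMINI, 223 in CasMINI and 708 ± 180 in LbCas12a, and then came KDELR1, a receptor gene of protein retrieval to the endoplasmic reticulum (chromosome 19, 48392892), with 126 ± 63.8, 546 and 168 ± 127. These ENOX2 and KDELR1 sites were the 2 candidate sites that LbCas12a and the CasMINI family shared.

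Candidate off-target sites numbered 756 for SpCas9, 35 for the CasMINI family and 26 for LbCas12a. Of reads at on-target plus off-target sites, off-target sites held 1.42% ± 0.195 in hpCasMINI (SD, n = 3), 1.04% in CasMINI (exact Clopper-Pearson 95% interval 0.967% to 1.11%), 8.59% ± 0.962 in LbCas12a and 83.5% ± 0.754 in SpCas9. The differences were -82.1 percentage points for hpCasMINI against SpCas9, -7.17 for hpCasMINI against LbCas12a and 74.9 for SpCas9 against LbCas12a, each with non-overlapping libraries and p = 0.1 in two-sided exact permutation tests, where 0.1 is the smallest p that 3 against 3 libraries allow. Each family was scored on its own list of sites, chosen in these same libraries, and the relabelings did not repeat that choice. The non-overlap and the p values between families are therefore no separate support for a difference. When every called site other than the target loci was counted as off-target, the difference between hpCasMINI and LbCas12a turned to 2.39 points (p = 0.6, exact permutation), that between hpCasMINI and CasMINI turned from 0.387 to -14.1 points, and that between hpCasMINI and SpCas9 was -44.4. A called CasMINI site needed 5 reads in 1 library and a called hpCasMINI site in 2 of 3, so the shares of these nucleases are then unlike measures. With loci called in every nuclease left out of the target loci, as the written clause has it, hpCasMINI differed from LbCas12a by -42.1 points and SpCas9 from LbCas12a by 45.2. With the 7 named loci alone as on-target, a setting added after the data were seen, the shares were 5.59% ± 0.895 in hpCasMINI, 3.23% in CasMINI (exact Clopper-Pearson 95% interval 3.01% to 3.46%), 9.46% ± 1.09 in LbCas12a and 85.1% ± 0.707 in SpCas9, and hpCasMINI then differed from LbCas12a by -3.88 points (p = 0.1, exact permutation). The site near TAS2R1 held 15408 of the 24398 off-target RPM of LbCas12a, more than LbCas12a had at EMX1 or near FGF18. The LbCas12a share thus rests largely on this site, and a share without it was not computed. Off-target sites with at least 5 reads numbered 24.7 ± 3.06 per hpCasMINI library and 22.7 ± 3.06 per LbCas12a library (p = 0.6, exact permutation), and 727 ± 2.08 per SpCas9 library. The CasMINI family had 15, 20 and 21 sites without hpCasMINI replicates 1, 2 and 3, the difference from LbCas12a then turned from 2 to -7.67, -2.67 and -1.67 sites per library, against 133 with every called site counted, and LbCas12a had 16 sites without its replicate 2. CasMINI had 4 of the family's sites, which were defined from hpCasMINI alone because CasMINI had 1 library of lower depth.

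**Figure D2:**
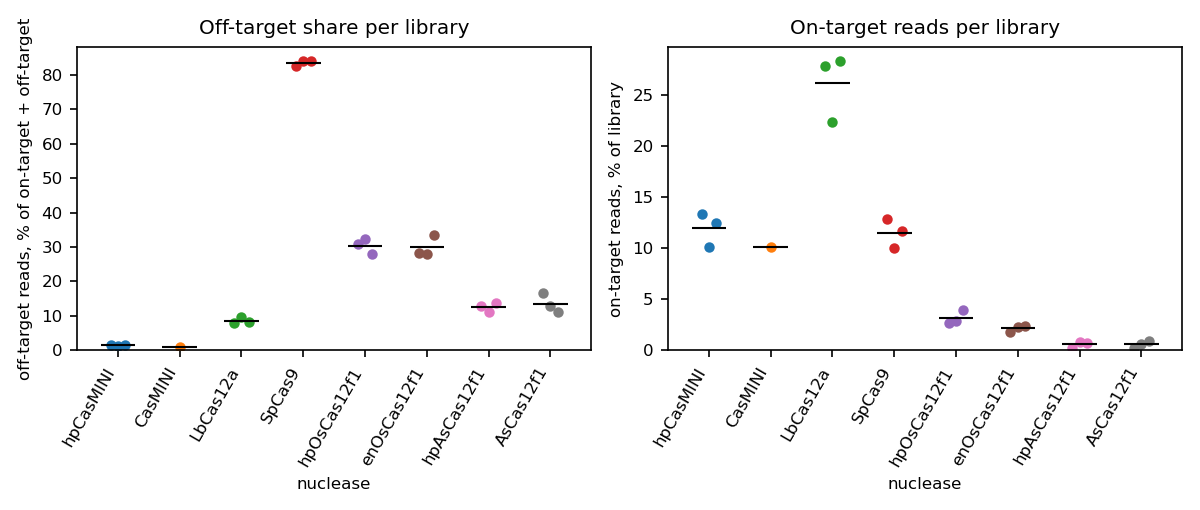
Off-target reads as percent of on-target plus off-target reads (left) and on-target reads as percent of the library (right), with a point per library and a bar at the mean of each nuclease. SpCas9 libraries sit near 83.5% off-target and hpCasMINI libraries near 1.42%.

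Site by site, hpCasMINI and SpCas9 differed most where only one of them had reads. SpCas9 had 6436 ± 373 RPM (SD, n = 3) at a site 245 bp from RNF19B (chromosome 1, 32964931), 4837 ± 166 in DLEU1 (chromosome 13, 50403141), 4325 ± 1067 on the unplaced contig GL000195.1 (83677), 3466 ± 504 in C1orf115 (chromosome 1, 220698589) and 3308 ± 218 in IGL, the immunoglobulin lambda locus (chromosome 22, 22785840). With 0 hpCasMINI reads, and 3 counts over the group as the floor, these were at least 11790-fold, 8860-fold, 7922-fold, 6349-fold and 6060-fold higher in SpCas9. In hpCasMINI, the site near CDC42EP4 had 3709 reads against 9 in SpCas9 (log2 fold 8.94), and RNU6-1, a U6 small nuclear RNA gene (chromosome 15, 67840015), rose by 0.90 on the log2 scale. The RNU6-1 difference turned to -0.87 when reads outside called sites set the library size, and its call was lost with the replicate numbers as a block (0.90) and in DESeq2 (0.07). Near CDC42EP4 the call was lost with reads outside called sites as library size (7.58) and with the replicate block (9.88), and the fold was 11.57 without SpCas9 replicate 2. The edgeR quasi-likelihood test called 250 of 155673 sites, 3 higher in hpCasMINI and 247 higher in SpCas9. Of the 250, 249 had non-overlapping libraries. Chance gives 10.0% at a site not chosen for a difference. These sites were called from the same libraries, so that count is no separate support. Since 95.2% of the tested sites had reads in 1 library, edgeR gave all sites the spread of its trend, and an adjusted p of a single site is not printed here. A fit limited to sites with reads in at least 3 of the 6 libraries, added after the data were seen, called 1097 sites, 249 of them among the 250, and DESeq2 called 815.

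Against LbCas12a, the site near TAS2R1 had 1 read in hpCasMINI and 45955 in LbCas12a (log2 fold -15.61). Sites with 0 hpCasMINI reads were higher in LbCas12a by at least 4274-fold near NCAN, 2828-fold in RNF213, 2179-fold at a site 10316 bp from LHX3, a pituitary homeobox gene (chromosome 9, 136185811), and 1898-fold in DDR2, a collagen receptor gene (chromosome 1, 162707022). The edgeR test called 15 of 145060 sites, 1 higher and 14 lower in hpCasMINI, and all 15 had non-overlapping libraries. As these sites were called from the same libraries, that is no separate support. DESeq2 called 49, of which 48 had reads in 1 library, edgeR with TMM factors called 6, and the fit limited to sites with reads in at least 3 libraries called 24. The calls in RNF213, near LHX3 and in DDR2 were lost with TMM factors and in DESeq2, that near NCAN was lost in DESeq2, and that in DDR2 also without the read filter, while the bounds rest on RPM and not on these fits.

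Between the reference nucleases, SpCas9 was higher than LbCas12a by at least 13567-fold at a site 29294 bp from B4GALT5 (chromosome 20, 49742676), where it had 13705 ± 906 RPM (SD, n = 3). The bounds were 12460-fold in SLC5A10 (chromosome 17, 18965777), 8161-fold in LEF1, a transcription factor gene of the Wnt pathway (chromosome 4, 108054183), 7777-fold at a site 53539 bp from HMX1 (chromosome 4, 8792006) and 7247-fold in OSTM1-AS1 (chromosome 6, 108156199). LbCas12a was higher by at least 3665-fold in RNF213, 2824-fold near LHX3, 2460-fold in DDR2 and 1532-fold where DHX8 and ETV4 overlap (chromosome 17, 43533948), while the site near TAS2R1 had 13 SpCas9 reads against 45955 in LbCas12a (log2 fold -12.84, and -15.88 without SpCas9 replicate 2). The edgeR test called 294 of 95408 sites, 274 higher and 20 lower in SpCas9, and 292 of these had non-overlapping libraries. Here too the sites were called from the same libraries, so that is no separate support. DESeq2 called 467 and the fit limited to sites with reads in at least 3 libraries called 945. With the replicate numbers as a block, edgeR called 0 sites, with 920 at an unadjusted p under 0.05. The log2 fold near TAS2R1, the named site with reads in both nucleases, was then -13.97. Same-numbered libraries of SpCas9 and LbCas12a correlated at 0.107, 0.0607 and 0.0965, not all above the 0.1 of the pairing check. Libraries with different numbers all lay lower, at -0.0835 to -0.0195, so a weak pairing remains possible.

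The third question was how hpOsCas12f1 compared with enOsCas12f1. Reads were higher in hpOsCas12f1 at each of 9 inferred target loci, with ratios from 1.09 to 2.05 and a median of 1.49. IL1RN, which encodes an interleukin receptor antagonist (chromosome 2, 113117531 to 113117960), had 6607 ± 1023 RPM in hpOsCas12f1 and 4446 ± 274 in enOsCas12f1 (SD, n = 3 each), and C17orf99 (chromosome 17, 78162181 to 78162582) had 4032 ± 856 against 2522 ± 472. A locus 10516 bp from C8orf74 (chromosome 8, 10711025 to 10711164) had 3628 ± 1677 against 1767 ± 268, LYPLAL1 (chromosome 1, 219198810) had 3495 ± 606 against 2434 ± 565, and a locus 132491 bp from SPEF2 (chromosome 5, 35485281) had 2034 ± 295 against 1327 ± 113. Libraries did not overlap at these 5 loci, where chance gives 10.0% per locus, and each had p = 0.1 in the two-sided exact permutation test. All loci were measured in the same libraries, so they do not count as separate tests of the pair. The libraries overlapped at NUDT16 (ratio 1.52), EMX1 (1.41), NLRC4 (1.32) and the acid-sensing channel gene ASIC2 (1.09, chromosome 17, 33337682), with exact permutation p from 0.3 to 0.6.

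Over the 10 loci, on-target reads were 3.13% ± 0.692 of hpOsCas12f1 reads and 2.15% ± 0.30 of enOsCas12f1 reads (SD, n = 3), a ratio of 1.46 (p = 0.1, exact permutation). The edgeR test called 4 of 53887 sites, all higher in hpOsCas12f1: the locus near C8orf74 (log2 fold 1.04), C17orf99 (0.68), IL1RN (0.57) and RNU6-1 (0.29), the last named after its values were seen because its libraries overlapped. For RNU6-1 the direction turned under DESeq2, at -0.11. DESeq2 called 0 sites, also 0 at an unadjusted p under 0.05, with log2 folds of 0.65 near C8orf74, 0.22 at C17orf99 and 0.14 at IL1RN. EdgeR called 0 with the replicate block, with 15 at an unadjusted p under 0.05 and folds of 0.95, 0.67 and 0.56, and 0 with reads required in at least 3 libraries, with 54 and folds of 1.04, 0.68 and 0.57. Without enOsCas12f1 replicate 1 the count was 2, with the calls at C17orf99 and IL1RN lost, and without enOsCas12f1 replicate 2 it was 1, with that near C8orf74 lost too. The call at C17orf99 was also lost with TMM factors (0.69) and without enOsCas12f1 replicate 3 (0.67), and that near C8orf74 without hpOsCas12f1 replicate 3 (0.61). Candidate off-target breaks of this family were strongest in IGF1R, the gene of an insulin-like growth factor receptor (chromosome 15, 98850461), at 1939 ± 92.9 in hpOsCas12f1 and 1277 ± 597 in enOsCas12f1, 10186 bp from USP43 (chromosome 17, 9739796), at 1264 ± 498 and 811 ± 186, and 85280 bp from RANBP3L (chromosome 5, 36387130), at 1087 ± 125 and 601 ± 284. Only the 10 sites with the most reads counted as target loci of this family. NUDT16 was among them, at 1944 and 1276 RPM, so IGF1R was left out by rank alone. The off-target share of the pair rests on that limit. The off-target share was 30.4% ± 2.17 in hpOsCas12f1 and 29.9% ± 3.09 in enOsCas12f1 (p = 1, exact permutation), and 67.0 ± 9.17 of the 135 candidate sites per hpOsCas12f1 library and 81.7 ± 2.89 per enOsCas12f1 library had at least 5 reads (p = 0.1, exact permutation). With 9 loci named here alone as on-target, a setting added after the data were seen, the difference in share turned from 0.457 to -0.0534 points (p = 0.9, exact permutation). At equal depth the difference in sites turned from -14.7 to 5.33 sites, it was -52.7 with every called site counted, and it was 2.5 without enOsCas12f1 replicate 1 and 7 without enOsCas12f1 replicate 3.

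The last pair was hpAsCas12f1 and AsCas12f1. IL1RN had the most reads of its 10 inferred target loci, with 1664 ± 829 RPM in hpAsCas12f1 and 1560 ± 1034 in AsCas12f1 (SD, n = 3 each). PCSK9, a regulator of the LDL receptor (chromosome 1, 55057401), had 789 ± 418 and 795 ± 489, and HEXA, a gene of lysosomal ganglioside breakdown (chromosome 15, 72368961), had 681 ± 400 and 711 ± 430. PDCD1, the gene of the PD-1 immune checkpoint receptor (chromosome 2, 241853432), had 506 ± 285 and 584 ± 380, and NLRC4 had 542 ± 281 and 604 ± 332. DOCK7 at its overlap with ANGPTL3 (chromosome 1, 62597584) had 408 ± 229 and 401 ± 263, APOB, the apolipoprotein B gene (chromosome 2, 21011655), had 351 ± 213 and 317 ± 196, and KLHL29 had 315 ± 205 and 312 ± 257. NUDT16 had 300 ± 158 and 238 ± 145, and PRKCA, a protein kinase C gene (chromosome 17, 66341396), had 131 ± 85.1 and 112 ± 112. Ratios ran from 0.866 to 1.26, with 6 loci higher and 4 lower, and exact permutation p values ran from 0.5 to 1.

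Over these loci, on-target reads were 0.569% ± 0.308 of hpAsCas12f1 reads and 0.563% ± 0.362 of AsCas12f1 reads (SD, n = 3), a ratio of 1.01 (p = 0.9, exact permutation), or 1.04 with the replicate block (p = 0.75, exact permutation). That ratio was 0.767 without AsCas12f1 replicate 1, 0.811 without hpAsCas12f1 replicate 2, 0.896 without hpAsCas12f1 replicate 3 and 1.5 without AsCas12f1 replicate 3. Replicate 1 of both stood apart, with 0.217% and 0.207% of reads on target. The edgeR test called 5 of 12908 sites, all lower in hpAsCas12f1, and 35 sites, 3 higher and 32 lower, with the replicate block, which the paired replicate numbers of these nucleases call for. All 5 were named after their values were seen: 4 of them, nearest IQCM (chromosome 4, 149142497), nearest HTR1E (chromosome 6, 86745358), in TET2-AS1 (chromosome 4, 105326562) and in SYT1 (chromosome 12, 78971818), had reads in 1 of the 6 libraries, and KHDRBS2 (chromosome 6, 62019182) had 4 against 514 reads (2.66 ± 4.61 against 339 ± 572 RPM). The KHDRBS2 log2 fold of -6.99 was -1.58, with the call lost, without AsCas12f1 replicate 2, and the call was also lost without hpAsCas12f1 replicate 2 (-6.44). None had non-overlapping libraries. DESeq2 called 0 sites, with 30 at an unadjusted p under 0.05, and edgeR called 0 with reads required in at least 3 libraries, with 131, and 0 without AsCas12f1 replicate 2, with 103, but 15 without hpAsCas12f1 replicate 3. Without replicate 1 of both, a setting added after the data were seen, it called 22. The off-target share was 12.6% ± 1.35 in hpAsCas12f1 and 13.5% ± 2.76 in AsCas12f1 (p = 0.9, and 0.75 with the replicate block, exact permutation), and 30.3 ± 6.43 and 28.3 ± 8.96 of the 50 candidate sites per library had at least 5 reads (p = 0.7, and 0.5 with the replicate block, exact permutation). The difference in share turned from -0.882 to 1.83 points with a minimum of 10 reads (p = 0.1, exact permutation), 0.624 at equal depth and 0.474 without AsCas12f1 replicate 1, and that in sites turned from 2 to -8.5 without AsCas12f1 replicate 1 and -0.5 without hpAsCas12f1 replicate 3. At equal depth the family had 12 candidate sites. The strongest candidate off-target site, outside the 10 sites kept as target loci, lay in LOC105379107 (chromosome 5, 103847579), at 90.7 ± 60.8 and 65.8 ± 58.4 RPM. It was followed by a site 1937 bp from TFPI2 (chromosome 7, 93883432), at 76.9 ± 45.7 and 51.1 ± 14.9, and by one in LOC105377622 (chromosome 4, 139600221), at 36.4 ± 27.4 and 51.7 ± 42.1.

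**Figure D3:**
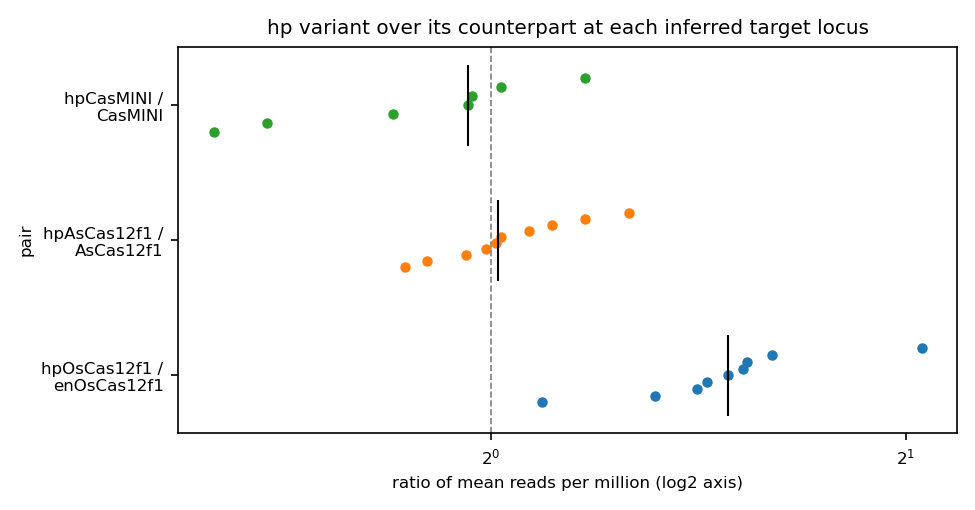
Ratio of mean RPM (log2 axis) of the hp variant over its counterpart, with a point per inferred target locus reported and a bar at the median. The 9 OsCas12f1 loci lie between 1.09 and 2.05, the 10 AsCas12f1 loci between 0.866 and 1.26 and the 7 CasMINI loci between 0.629 and 1.17.

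The ends of the breaks at the target loci differed between nucleases. The distance from the left end to the right end, over loci and libraries, had a median of -2.5 bp in SpCas9 and in LbCas12a, which is an overlap of the mapped ends. It was 2 bp in hpCasMINI and in CasMINI, 4 bp in hpOsCas12f1, 3.5 bp in enOsCas12f1, 10.5 bp in hpAsCas12f1 and 9 bp in AsCas12f1. Between quartiles it ran from -4 to -1 bp in SpCas9, from -5.25 to 0 bp in LbCas12a, from 0.75 to 4.25 bp in hpCasMINI and from 8 to 14 bp in hpAsCas12f1. The PAM distance of the design was not analysed here, and these differences were not tested.

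Called sites numbered 528 for hpCasMINI, 457 for CasMINI, 334 for LbCas12a, 1446 for SpCas9, 233 for hpOsCas12f1, 306 for enOsCas12f1, 869 for hpAsCas12f1 and 913 for AsCas12f1. Of the 3112 sites called in any nuclease, 60 were called in all 8 and 859 in the AsCas12f1 pair alone, and reads faced each other at 84.3% of those 859. With a library left out, both remaining libraries had to hold the reads. The counts fell to 346, 272 and 285 for hpCasMINI without replicates 1, 2 and 3, to 177, 184 and 181 for enOsCas12f1 without replicates 1, 2 and 3, and to 211 for LbCas12a without replicate 1. They fell to 135 and 144 for hpOsCas12f1 without replicates 2 and 3, to 552 for hpAsCas12f1 without replicate 2, and to 478 and 471 for AsCas12f1 without replicates 2 and 3. At equal depth, the nucleases with 3 libraries had from 123 called sites (hpCasMINI) to 659 (SpCas9), while sets of 3 libraries mixed from 3 families had 96 to 115.

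Background hotspots called in every nuclease were led by RNU6-1, with 113216 ± 19986 RPM in LbCas12a (SD, n = 3), 54794 ± 1034 in hpCasMINI and 28119 ± 16442 in hpAsCas12f1. Its reads faced each other in all 22 libraries, opposite to the arrangement of a two-sided break. The mitochondrial genome, joined into a single site named for RNR2, a mitochondrial rRNA gene, had 1530 ± 222 in hpCasMINI and 5940 in CasMINI. A site 402257 bp from PROS1 (chromosome 3, 93470357) had 1122 ± 150 in hpCasMINI and 1769 ± 210 in hpAsCas12f1. Near the ends of chromosomes, a site in LOC124905564 (chromosome 1, 9996) had 1493 ± 377 in hpCasMINI and 34.0 ± 26.6 in hpAsCas12f1, and a site 51053 bp from DUX4 (chromosome 4, 190122442) had 1387 ± 529 and 89.4 ± 59.9.

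Sites called in no nuclease had a share in MCF7 amplicon genes of 1.40 ± 0.245 times the share of chromosome length (SD, n = 22 libraries), with ZNF217 at 3.65 ± 1.95 and VMP1 at 2.09 ± 0.799. Common fragile site genes had a ratio of 0.956 ± 0.0487, with FHIT at 0.437 ± 0.0787, LRP1B at 0.514 ± 0.142 and WWOX at 0.576 ± 0.117 below 1 in all 22 libraries, while DLG2 had 1.53 ± 0.235 and CTNNA3 had 1.34 ± 0.221. Genes often used to test nucleases had 1.42 ± 0.314, and 1.21 when sites within 5 kb of the target loci were left out, an alternative added after the data were seen. Cancer genes had 1.23 ± 0.220 and luminal genes 1.09 ± 0.225. The p of Fisher's exact test, with the predicted counts entered as a second sample, was under 0.05 in 9 of 22 libraries for amplicon genes, 5 for fragile site genes, 8 for nuclease-test genes, 6 for cancer genes and 0 for luminal genes. Among 25 comparisons of a list between nucleases, 6 reached the exact permutation p of 0.1, and the lowest Benjamini-Hochberg adjusted p was 0.357. The annotated length includes unsequenced gaps, so 1 is not the value of an even spread, and no reference over all genes was computed.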

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

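All tests in this part were chosen only after the results were seen.

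A signal outside the comparisons appeared at 859 sites that were called in the AsCas12f1 pair and in no other nuclease, which held 2.19% to 13.7% of the reads of those 6 libraries (lowest in replicate 1 of both, at 2.19% and 3.28%) and 0.0113% to 0.105% of the other 16. Breaks at guide-matched sites are argued against for most of them, since rightward reads started left of leftward reads at 724 sites, or 84.3%, an arrangement found in 0 of 20 values at the target loci of the pair, which had been chosen for the opposite one, and in 11.5% of values after the orientations were shuffled within sites. Facing reads were not particular to these sites. Their share of all called sites was 74.6% in CasMINI, 67.1% in LbCas12a and 62.1% in hpCasMINI. It was 49.8% in hpOsCas12f1, 47.1% in enOsCas12f1 and 24.1% in SpCas9, and 48.4% of simulated sites with spread positions were called facing. For chance recurrence of background positions, 76.6% of the 859 sites had reads in at least 5 of the 6 libraries, which cannot decide. The sites were called for having reads in at least 2 libraries, and no share expected by chance was computed. It also stays open whether short stretches of other DNA present in these libraries were placed on the genome by the aligner, which fits the median distance of 19 bp between the facing starts (5th to 95th percentile 15 to 62 bp). The sequence of the reads was not in the sources, so neither the origin of such DNA nor guide-matched breaks at the sites without facing reads were tested.

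A second signal outside the comparisons was the RNU6-1 site, which held 0.916% to 13.6% of the reads of every library, the highest share being in LbCas12a replicate 2. Breaks at the locus itself are argued against, since rightward reads started left of leftward reads in all 22 libraries, opposite to the arrangement of a two-sided break. Promoter sequence of the guide plasmids, placed on the genome by the aligner, may be the source: at least 99.4% of the site's reads lay between the most used starts in 21 libraries, but the share was 56.2% in hpOsCas12f1 replicate 2, where both most used starts lay further inward. A window common to all libraries, a second measure taken after that miss, held at least 99.8% of the reads in each, so plasmid and genomic promoter DNA cannot be told apart without the read sequences. No biological explanation was tested for the differences between nucleases at this site.

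Of the LbCas12a candidate off-target sites, 2 were also candidate sites of hpCasMINI, the one nearest ENOX2 and the one in KDELR1. Reads of LbCas12a libraries assigned to hpCasMINI libraries are argued against, because the ratio of RPM in hpCasMINI over LbCas12a was 0.308 and 0.751 at these sites and at most 0.000527 at the 5 strongest LbCas12a sites that were not shared, at least 584 times lower. For chance overlap, a share of 0.00451 of the 100000 random placements gave as many shared sites, but that test cannot decide. The 520 called hpCasMINI sites outside the target loci hold only these 2 LbCas12a sites to draw from, which fixes much of its outcome. The left ends lay close together at these 2 sites, but sites were joined within 50 bp and no distance expected by chance was computed. Left ends in hpCasMINI and LbCas12a were 48393001 and 48393004 in KDELR1, and 130565412 and 130565416 near ENOX2. SpCas9 had 0.481 RPM in KDELR1 and 0.321 near ENOX2. Guides that target the same positions may share similar sequences elsewhere, a biological explanation that was not tested because no guide sequences were available.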

How the results depend on the processing

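Fits with reads in at least 3 of the 6 libraries, the settings without replicate 1 of both AsCas12f1 nucleases, the 5-fold and 20-fold criteria, the two-sided count, the written clause, reads without the RNU6-1 site, loci also broken in another family, only target loci named in the text and gene lists away from target loci were chosen only after the data were seen, and the other settings were planned. The limits of these data are depth, the few libraries and the missing sequences. Off-target counts rest on a read minimum, so a site of a shallow library can fall below it, and at equal depth the number of called sites fell for every nuclease. The exact permutation test used for single values cannot pass 0.05 in 3 against 3 libraries, and CasMINI with 1 library has no test against hpCasMINI. The alternative of at most 4 mismatches was not run, since neither guide sequences nor a genome were in the sources.

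Several results kept their direction under every alternative run on them. The difference in off-target share ran from -87.3 to -44.4 percentage points for hpCasMINI against SpCas9 and from 45.2 to 75.6 for SpCas9 against LbCas12a. The on-target ratio ran from 1.29 to 1.57 for the OsCas12f1 pair. SpCas9 candidate off-target sites numbered 560 to 842. The ratios of the 5 gene lists stayed on the same side of 1, within 1 SD of the value reported. Of the values that answer a comparison, 392 kept their direction and their side of the threshold, or stayed within 1.5 times for a count, 105 moved further without turning and 42 turned direction. Of those at single sites and loci, 559 stayed, 45 lost the call and 29 turned. Of the values that stayed, 203 and 192 came from permutation tests whose smallest p is 0.1, so that their side of the threshold was fixed by the design and only their direction could change. For the values below the cause was not tested, except where fewer reads or libraries lower a count by construction.

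Called sites depended on the read, orientation and geometry rules. With a minimum of 2 reads they numbered 925 for hpCasMINI, 771 for CasMINI, 567 for LbCas12a, 398 for hpOsCas12f1, 563 for enOsCas12f1, 2811 for hpAsCas12f1 and 1990 for AsCas12f1. A minimum of 10 reads gave 346 for hpCasMINI, 299 for CasMINI, 146 for hpOsCas12f1, 176 for enOsCas12f1, 526 for hpAsCas12f1 and 567 for AsCas12f1. Reads required in all 3 libraries gave 206 for hpCasMINI, 196 for LbCas12a, 115 for hpOsCas12f1, 127 for enOsCas12f1, 503 for hpAsCas12f1 and 423 for AsCas12f1. Without the orientation rule there were 902 for hpCasMINI, 19306 for CasMINI, 643 for LbCas12a and 1398 for AsCas12f1. Two-sided breaks alone numbered 130, 76, 62, 100, 127, 120 and 109 for hpCasMINI, CasMINI, LbCas12a, hpOsCas12f1, enOsCas12f1, hpAsCas12f1 and AsCas12f1. At equal depth there were 123 for hpCasMINI, 179 for CasMINI, 147 for LbCas12a, 659 for SpCas9, 173 for enOsCas12f1, 427 for hpAsCas12f1 and 500 for AsCas12f1.

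Candidate off-target sites of the OsCas12f1 family, 135 as reported, numbered 206 with a minimum of 2 reads, 63 with 10 reads, 40 with reads required in all 3 libraries, 87 with the 20-fold criterion and 79 at equal depth. For the AsCas12f1 family, 50 as reported, the counts were 15 with 10 reads, 17 with all 3 libraries, 109 and 11 with the 5-fold and 20-fold criteria and 12 at equal depth. For the CasMINI family, 35 as reported, they were 4 with all 3 libraries, 22 with sites joined within 25 bp, 59 and 15 with the 5-fold and 20-fold criteria and 10 at equal depth. LbCas12a, 26 as reported, had 16 with all 3 libraries and 16 at equal depth.

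Differences are given below as the hp nuclease minus the other. The on-target ratio of hpCasMINI over CasMINI, 1.18 as reported, turned to 0.922 with only target loci named in the text. For hpCasMINI against LbCas12a, the difference in off-target sites per library, 2 as reported, turned to -12 with all 3 libraries, -8 with sites joined within 25 bp, -0.667 with the written clause, which leaves out loci called in every nuclease, -8 with the 20-fold criterion and -7.67 at equal depth, while counting all called sites that were not on target raised it to 133. Counting all called sites that were not on target turned the difference in share from -7.17 to 2.39 points, and the written clause moved it to -42.1. For hpCasMINI against CasMINI, the difference in share, 0.387 points as reported, was -0.122 with all 3 libraries, -14.1 with all called sites that were not on target, 0.187 with the 20-fold criterion, 2.35 with only target loci named in the text and 0.0651 at equal depth. The difference in sites per library, 20.7 as reported, was 0 with all 3 libraries, 12 and 25 with sites joined within 25 bp and 100 bp, -36.3 with all called sites that were not on target, 35.7 and 7.33 with the 5-fold and 20-fold criteria and 4.67 at equal depth. CasMINI sites were called from 1 library, so the 2 values with all called sites set unlike measures side by side.

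Within the OsCas12f1 pair, the difference in share, 0.457 points as reported, turned to -1.55 with sites joined within 25 bp, -3.51 with all called sites that were not on target, -0.0534 with only target loci named in the text and -0.224 with the written clause. Its difference in sites per library, -14.7 as reported, turned to 0.333 with a minimum of 10 reads, 1.33 with all 3 libraries, 1.67 with the 20-fold criterion and 5.33 at equal depth, and was -52.7 with all called sites that were not on target. Within the AsCas12f1 pair, the difference in share, -0.882 points as reported, turned to 1.83 with 10 reads, 0.267 with all 3 libraries, 0.556 without replicate 1 of both, 0.647 with the 20-fold criterion and 0.624 at equal depth, and was -2.47 with only loci also broken in another family. Its difference in sites per library, 2 as reported, turned to -2 with a minimum of 2 reads, -1.5 without replicate 1 of both and -2.67 with all called sites that were not on target. Per reads outside called sites, the on-target ratio of that pair turned from 1.01 to 0.955, that of DOCK7 from 1.02 to 0.961 and that of KLHL29 from 1.01 to 0.952, and at equal depth PCSK9 turned from 0.992 to 1.07.

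For the AsCas12f1 pair the count of sites that edgeR called went from 5 to 8 with TMM factors, 9 without the read filter, 22 without replicate 1 of both and 35 with the replicate block, and to 0 with reads in at least 3 libraries (131 at an unadjusted p under 0.05) and 0 in DESeq2 (30). For the OsCas12f1 pair the count fell from 4 to 0 with the replicate block (15 at an unadjusted p under 0.05), 0 with reads in at least 3 libraries (54) and 0 in DESeq2 (0), and in DESeq2 the log2 fold of RNU6-1 turned from 0.29 to -0.11. For hpCasMINI against SpCas9, 250 as reported, DESeq2 called 815 and the fit with reads in at least 3 libraries called 1097, and the log2 fold of RNU6-1 turned from 0.90 to -0.87 with background reads as library size. For hpCasMINI against LbCas12a, 15 as reported, the counts were 6 with TMM factors, 49 in DESeq2 and 24 with reads in at least 3 libraries. For SpCas9 against LbCas12a, 294 as reported, they were 467 in DESeq2, 945 with reads in at least 3 libraries and 0 with the replicate block (920 at an unadjusted p under 0.05). With the replicate block, on-target ratios were 1.44 for the OsCas12f1 pair (exact permutation p = 0.25) and 1.04 for the AsCas12f1 pair (exact permutation p = 0.75), where 0.25 is the smallest p that this design allows.

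Each library was also left out in turn. Called sites then ran from 272 to 346 for hpCasMINI, 211 to 250 for LbCas12a, 177 to 184 for enOsCas12f1, 135 to 166 for hpOsCas12f1, 471 to 769 for AsCas12f1 and 552 to 676 for hpAsCas12f1, since both remaining libraries had to hold the reads. Candidate off-target sites ran from 15 to 21 for the CasMINI family and from 16 to 22 for LbCas12a. For hpCasMINI against CasMINI, the difference in share was 0.121, 0.262 and 0.159 without hpCasMINI replicates 1, 2 and 3, and that in sites per library ran from 11 to 17. For hpCasMINI against LbCas12a, the difference in sites per library ran from -7.67 without hpCasMINI replicate 1 to 8 without LbCas12a replicate 2, and it was negative without any one of the hpCasMINI libraries. In the OsCas12f1 pair, the difference in share was -0.802, -1.20 and 3.87 without enOsCas12f1 replicates 1, 2 and 3, and 0.170, -1.20 and -0.404 without those of hpOsCas12f1. Its difference in sites per library ran from -30 without hpOsCas12f1 replicate 2 to 7 without enOsCas12f1 replicate 3, and was 2.5 without enOsCas12f1 replicate 1.

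In the AsCas12f1 pair, the on-target ratio ran from 0.767 without AsCas12f1 replicate 1 to 1.5 without AsCas12f1 replicate 3, and was 0.811 and 0.896 without hpAsCas12f1 replicates 2 and 3. The difference in share ran from -1.72 without AsCas12f1 replicate 3 to 0.474 without AsCas12f1 replicate 1. That in sites per library ran from -8.5 without AsCas12f1 replicate 1 to 7.67 without hpAsCas12f1 replicate 1, and was -0.5 without hpAsCas12f1 replicate 3. Each of the 10 loci had ratios on both sides of 1: PCSK9 from 0.757 to 1.43, DOCK7 from 0.765 to 1.51, HEXA from 0.745 to 1.40, PRKCA from 0.787 to 2.60, APOB from 0.823 to 1.49, KLHL29 from 0.731 to 1.79, NLRC4 from 0.683 to 1.25, IL1RN from 0.811 to 1.63, PDCD1 from 0.655 to 1.29 and NUDT16 from 0.938 to 1.66. The highest ratios came without AsCas12f1 replicate 3, except at APOB, where it came without hpAsCas12f1 replicate 1. The lowest came without AsCas12f1 replicate 1, except at PRKCA and NLRC4, where it came without hpAsCas12f1 replicate 2. EdgeR called from 0 sites without AsCas12f1 replicate 2 (103 at an unadjusted p under 0.05) to 15 without hpAsCas12f1 replicate 3, and for the OsCas12f1 pair from 1 without enOsCas12f1 replicate 2 to 6 without hpOsCas12f1 replicate 1, with 2 without enOsCas12f1 replicate 1.

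Regrouping the 6 libraries of each edgeR comparison into 3 against 3 gives 10 splits, too few for a share under 0.05. All splits were fitted without the replicate block, so they do not bear on the 35 sites called with it in the AsCas12f1 pair. Of those 35, 5 had reads in fewer than 3 libraries. The hpCasMINI comparison with SpCas9 called 250 sites in the real split and 0 at most in the others, that with LbCas12a called 15 against 0, and SpCas9 against LbCas12a called 294 against 0, so that 1 split of each had as many. The OsCas12f1 pair had 4 sites in the real split and 5 at most in the others, and 5 of its splits had at least 4. For the AsCas12f1 pair all 10 splits had at least the 5 sites of the real one, and the highest other, 17, came from hpAsCas12f1 replicates 1 and 2 with AsCas12f1 replicate 2 and its cause was not tested. The 3 other splits that part as many of the same-numbered pairs as the real one, all 3, gave 5 sites each, while the splits that part 1 pair gave 5 to 17.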

Other observations

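No test in this part was planned; the comparison of the 2 pairs below was chosen only after the pairs were seen. The strength of candidate off-target sites differed in range between families, taking for each site the higher mean of the nucleases with 3 libraries in its family. Of the 756 SpCas9 sites, 352 had at least 100 RPM and 118 at least 1000, with a median of 79.1. LbCas12a had a similar median of 82.0, with 11 of its 26 sites at 100 RPM or more and 5 at 1000 or more. Medians were 27.98 RPM in the OsCas12f1 family, 15.5 in the AsCas12f1 family and 15.4 in the CasMINI family. In those families 29 of 135, 0 of 50 and 3 of 35 sites had at least 100 RPM. The 10-fold criterion with its floor of 1 RPM keeps out sites under 10 RPM, and the minimum of 5 reads stands for more RPM in shallow libraries. Medians therefore depend in part on the rule and on depth. The first position of a candidate site lay inside a protein-coding, snRNA or lncRNA gene in 484 of 756 cases for SpCas9 and 15 of 26 for LbCas12a. It did so in 21 of 35 cases for CasMINI, 79 of 135 for OsCas12f1 and 23 of 50 for AsCas12f1. No share over the genome was computed for comparison. Apart from the sites near ENOX2 and in KDELR1, no candidate site was shared between families, and the 10-fold criterion works against such sharing.

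Reads outside all called sites made up 20.03% to 31.7% of SpCas9 libraries, 56.6% to 59.1% of LbCas12a libraries, 77.1% to 81.7% of CasMINI and hpCasMINI libraries, 86.3% to 90.8% of the OsCas12f1 pair and 79.9% to 95.4% of the AsCas12f1 pair. Among single genes of the lists, background sites exceeded the share of length in 20 of 22 libraries for POLQ, a DNA polymerase gene of end joining (1.77 ± 0.769, SD), in 19 for BRCA1, a gene of homologous recombination (1.52 ± 0.675), and in 18 for KRT8, a luminal keratin gene (2.41 ± 1.42). GRID2, a glutamate receptor gene of the fragile site list, was below it in all 22 libraries (0.661 ± 0.138), and ESR1, the estrogen receptor gene, was above it in 2 (0.778 ± 0.275). These genes were named after their values were seen.

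The ratio of hp nuclease over counterpart was set side by side in the OsCas12f1 and AsCas12f1 pairs. On-target reads had ratios of 1.46 and 1.01, a ratio of ratios of 1.44, with p = 0.48 in an exact permutation test over 400 relabelings of libraries within pairs and p = 0.25 over the 160 that swap AsCas12f1 libraries only within a replicate number. Off-target shares had ratios of 1.02 and 0.935, a ratio of ratios of 1.09 (p = 0.64 and 0.588 in the same exact permutation tests). A difference between the pairs was thus not detected with 3 libraries per nuclease.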
